A study of Ovis aries with 20 samples.

How the data were processed

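Blood was collected into tubes that stabilise RNA, RNA was extracted, purified, amplified and labelled with Cy3 by Agilent's one-colour protocol, and hybridised to an array of 45220 features for sheep, per the labels' protocols. The samples are 10 basal and 10 supplemented, 1 array each. The group of each sample comes from the labels. The labels give an age of the ewes that differs from the one in the series' design text, and no age is used here. The design text says that each ewe was her own control, so the 10 samples of a group are 10 animals, but no label says which animal a sample came from.

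The values are linear probe intensity as deposited by the authors in a normalized table; scanner software, background correction and normalization method are not given in the sources used here. Sorted by size, the 20 columns lie close together at high ranks: the coefficient of variation between arrays was 2.55%, 0.46% and 0.95% at ranks 1000, 10000 and 20000 from the top, and 14.9% at rank 30000, among dim spots. No measured value lies below 2. A second deposited table holds the same intensity values (largest difference 0). Empty cells make up 8.19% to 24.3% of the spots of gene probes per array, by a rule that is not stated. They are mostly dim probes (30.9% of cells of probes with a mean under 6 on the log2 scale are empty), but 1.00% of the cells of probes over 8 are empty too. No flag for background or saturation was used here.

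Control features were left out. Intensities were put on log2 with no offset, empty cells were left missing, and spots of the same probe were averaged. A probe entered when it was measured on at least 5 of the 10 arrays in each group, which left 35832 of 43353 probes. The log2 values of a gene's probes were averaged after each probe's own mean over its measured arrays was removed. A missing cell then does not shift the gene by the difference in level between its probes. It can still shift the gene where the groups lack unequal numbers of cells. IP6K3, for example, had a log2 fold change of 1.44, outside those of its probes (1.49 and 1.47). Gene symbols are those of the deposited table. Of 15057 symbols, 88.2% were found as symbol or synonym in the RefSeq gene table of the assembly ARS-UI_Ramb_v3.0, used only for this check. Probes without a symbol (10035) count only among probes, and 23 names that a spreadsheet had turned into dates were left out. Coordinates and probe sequences were not used, so length and GC content were not examined. The handling of empty cells was chosen after seeing the files.

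Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg), and a gene is called at an adjusted p under 0.05. The 24 gene lists, the rule for named genes and the tests of genes, lists and cell type scores between the groups were fixed before the data were examined. The tests on basal replicate 7, on the bounds of the cell type scores and on gene families were chosen later. Named are the 10 genes with the largest rise and the 10 with the largest fall among those called, the 5 with the smallest p in each direction, every measured selenoprotein gene, and up to 4 members with the smallest p of every other list; some of the genes this rule names are not used here. Lists were tested with camera at its preset correlation of 0.01, beside camera with a correlation estimated on genes measured on all arrays, and fry. Fry used only the genes measured on all 20 arrays, which left DIO2, DIO3, GPX6 and SEPN1 out of the selenoprotein list. By fry, 5 lists moved 1 way on balance at an adjusted p under 0.05: selenoproteins (0.000135), heat shock and chaperones (0.0033), the respiratory chain (0.020), glycolysis (0.023) and apoptosis and its regulators (0.036). Fry does not compare a list with other genes. Among the selenoprotein genes it used, only SEPW1 and TXNRD1 were called (log2 fold changes of 0.99 and 0.28). SEPHS2 alone went the other way (-0.22). Its small p for selenoproteins is therefore not a rise of each member. A list score is the mean over its genes of the log2 value minus the gene's mean. Cell type scores were compared by a two-sided permutation test with 100000 resamples, adjusted over the 8 types.

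The limma step was tested on simulated gene values with the means, spread and empty cells of these 14149 genes and 50 genes changed by each of 4 folds. It recovered 28%, 56%, 82% and 98% of the genes changed 1.25-fold, 1.5-fold, 2-fold and 3-fold, with 4 false calls among 136. The simulated noise was independent between genes and arrays, with no animal pairs and no slide effect. The probe filter and the averaging of probes were not part of it. The 4 false calls therefore do not measure those of the real comparison. Arrays within a group correlated at r of 0.978 or more across probes, and no arrays were identical.

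The title numbers run from 1 to 10 in the basal group and from 11 to 20 in the supplemented group. Whether they pair the samples (number n with n + 10) was checked: the deviations from the group mean, over 22893 probes measured on all arrays, correlated at r of 0.34 to 0.63 within the 10 assumed pairs and at -0.32 to 0.15 in the 90 other combinations. All 10 samples of each group correlated best with their assumed partner. The pairing comes from this check and the design text, not from a label. The alternatives were the second table, other normalizations, other handling of empty cells and dim probes, the brightest probe per gene, other variance models, array weights, the replicate block, the slide as a random block (correlation within slides 0.049), the spike-in signal as a covariate, leaving out samples, and a Wilcoxon test.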

Results

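Whole blood of 10 lactating crossbred ewes was profiled before and after a change of diet. Each ewe was sampled at day 0, at the end of a period on a basal diet with 0.13 mg selenium per kg of dry matter, and again at day 40, after supplementation to 0.45 mg selenium per kg of dry matter (1.40 mg per animal per day in the sample labels). Selenium is the trace element that enters selenoproteins as the amino acid selenocysteine. The 20 samples form a basal group of 10 and a supplemented group of 10, each sample on 1 array of the one-colour Cy3 type. No ewe stayed on the basal diet until day 40 in the samples used here, so the diet, the 40 days between samplings and the course of lactation all differ between the groups, and each difference below is one between day 40 and day 0. The arrays measured 75.7% to 91.8% of the spots of gene probes, and their number limits the precision. After probes with too few measurements were left out, 14149 genes with a symbol entered the comparison.

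The question of the design is which blood transcripts differ after selenium supplementation. At day 40, SEPW1, which encodes selenoprotein W, was 1.99-fold higher, RELA, which encodes the p65 subunit of NF-kappa-B, was 1.64-fold higher, and PPP4R1, which encodes a regulatory subunit of protein phosphatase 4, was 2.55-fold higher. PTBP1, which encodes a splicing regulator that binds polypyrimidine tracts, rose 1.55-fold, and CCND3, which encodes cyclin D3, rose 1.59-fold. These 5 genes had the smallest unadjusted p among those that rose, share an adjusted p of 4.4e-05 with further genes, and each was higher in 10 of 10 pairs of samples taken by their title numbers. Among the genes that fell, PSMB3, which encodes a beta subunit of the 20S proteasome, was 1.41-fold lower (adjusted p = 4.4e-05). COX7A1, which encodes a subunit of cytochrome c oxidase, was 1.56-fold lower (adjusted p = 0.00026). FAM35A, AAGAB and APITD1 were 1.36-fold, 1.33-fold and 1.42-fold lower, with adjusted p of 6.8e-05, 7.2e-05 and 0.00037. All probes of these 10 genes moved in the direction of their gene.

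In log2 intensity, SEPW1 went from 10.52 ± 0.24 in the basal samples to 11.51 ± 0.25 in the supplemented samples (SD, n = 10 each), a log2 fold change of 0.99 ± 0.11 (SE). RELA went from 6.64 ± 0.20 to 7.35 ± 0.13, a log2 fold change of 0.72 ± 0.078. PTBP1 went from 6.33 ± 0.13 to 6.96 ± 0.14, and its 4 probes gave log2 fold changes between 0.59 and 0.69. PPP4R1 went from 4.90 ± 0.48 to 6.25 ± 0.085, with basal replicate 7 at 6.09 close to the supplemented samples. PSMB3 went from 13.27 ± 0.11 to 12.78 ± 0.12, a log2 fold change of -0.50 ± 0.058. Setting the empty cells of the deposited values to 2, just below the lowest measured value, ended the calls of SEPW1 (log2 fold change 1.45, adjusted p = 0.087), PTBP1 (0.96, adjusted p = 0.15), PPP4R1 (0.76, adjusted p = 0.39) and AAGAB (-0.79, adjusted p = 0.23). Centring each array on its own median ended the calls of all 5 genes that fell: PSMB3 (-0.47, adjusted p = 0.15), COX7A1 (-0.62, 0.115), APITD1 (-0.48, 0.13), FAM35A (-0.41, 0.23) and AAGAB (-0.39, 0.27). The value of 2 gives a bright gene a very low value wherever a spot is empty, as for SEPW1 in basal replicate 7. The adjusted p of SEPW1 over all 17 alternatives ran from 7.8e-06 to 0.087.

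**Figure D1:**
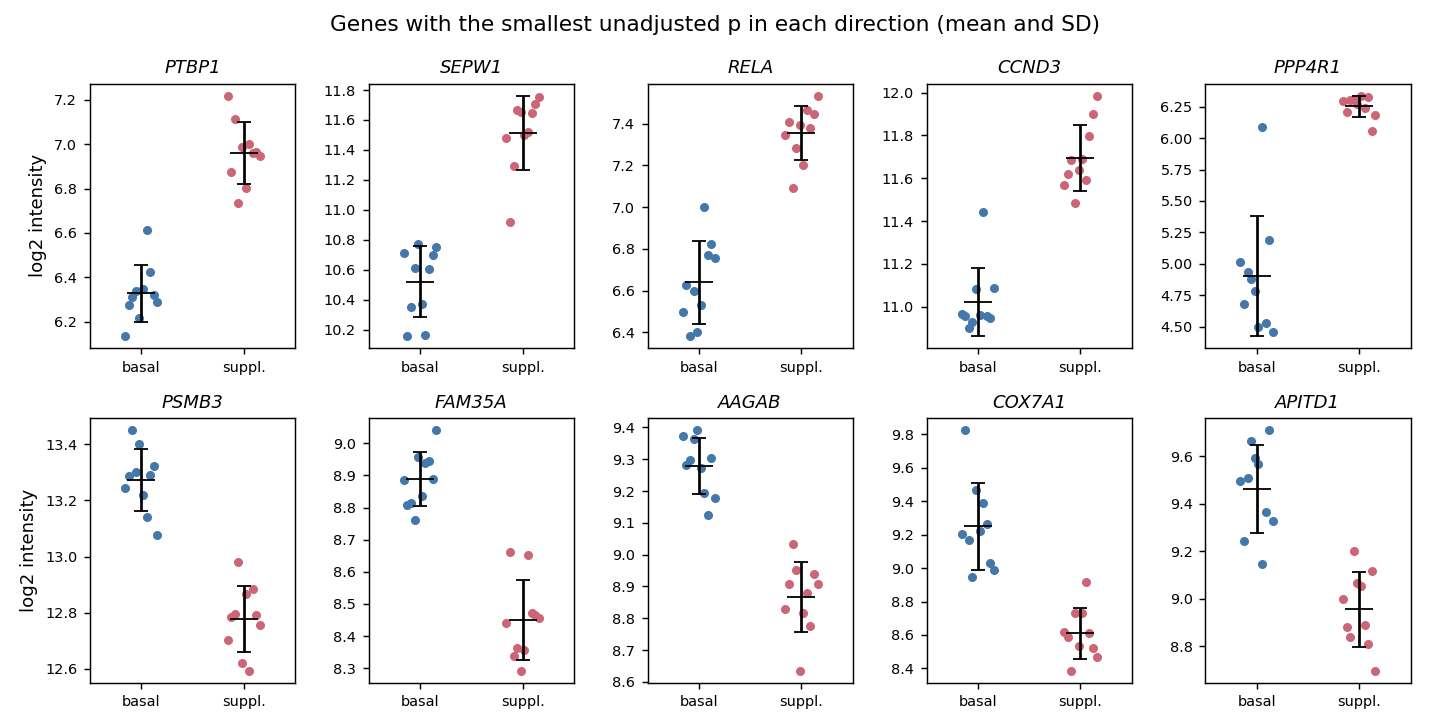
Log2 intensity (vertical axis) of the 5 genes with the smallest unadjusted p in each direction, in 10 basal samples at day 0 (blue) and 10 supplemented samples at day 40 (red); each point is a sample, and the bars give the mean and SD. SEPW1 rose by 0.99 and PSMB3 changed by -0.50 on the log2 scale, both with an adjusted p of 4.4e-05.

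Over all genes, 1725 of the 14149 changed at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg), 1028 higher and 697 lower at day 40. Of these, 349 changed by at least 1.5-fold, and the median absolute log2 fold change of the 1725 genes was 0.39. Of the 1564 called genes with 2 or more probes, 1538 had all probes in 1 direction (98.3%, against 70.8% of all genes with 2 or more probes). A gene is called on the mean of these same probes, so the selection itself favours such agreement. On single probes, with unnamed probes included, 4405 of 35832 changed. With the title numbers taken as animals in a block, 3135 genes changed (1668 higher and 1467 lower) and 8055 probes, and 1655 of the 1725 genes were called again in the same direction. Repeating quantile normalization over all cells left 401 genes, 355 higher and 46 lower, and centring each array on its own median left 161, 143 higher and 18 lower. Both treat the empty cells as missing at random, although dim probes have most of them. The same steps on the probes measured on all 20 arrays gave 1678 and 1717 genes, with 977 and 991 higher. The medians of these probes already lay between 8.26 and 8.28 on the log2 scale on every array. Centring on them could therefore change little, and its count does not weigh against the smaller counts.

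The largest fold changes among called genes belonged mostly to genes of low signal. DPT, which encodes the extracellular matrix protein dermatopontin, went from 1.48 ± 0.099 (n = 10) to 3.52 ± 0.996 (n = 8), 4.11-fold higher (adjusted p = 0.00029 from limma). Its probes differed, with log2 fold changes of 2.41 and 1.06 (limma on single probes, adjusted p = 4.5e-05 and 0.071). Adenylate cyclase 6 (ADCY6) rose 3.58-fold (adjusted p = 0.0015) and the microfibril gene MFAP5 rose 2.92-fold (adjusted p = 0.0017). The basal values of these genes lie near the lowest of the arrays, so the folds depend on the offset: with 16 added before log2, the log2 fold changes of DPT, ADCY6 and MFAP5 were 0.63, 0.58 and 0.58, against 2.04, 1.84 and 1.55 without it. SPAG17, NRG3, LUZP2, PRSS55, IP6K3 and ACADL rose between 2.59-fold and 3.42-fold with adjusted p from 0.0088 to 0.049. PRSS55 and IP6K3 each had 1 probe that did not pass on its own (limma on single probes, adjusted p = 0.14 and 0.17). Without the offset, the largest fall was that of CAPN8, a calpain protease gene, from 4.58 ± 0.28 (n = 7) to 2.94 ± 0.65 (n = 5), 3.11-fold lower (adjusted p = 0.00145 from limma). With 16 added its log2 fold change was -0.73, against -1.64 without it. That of TMEM184A stayed at -0.769 or lower in all 17 alternatives, so the order of the falls depends on the offset. MCF2L, OR6Y1, CREB5, ICAM5, ACTH-R and SSTR1 fell between 1.99-fold and 2.42-fold. The probes of MCF2L gave log2 fold changes of -1.97 and -0.60 (limma on single probes, adjusted p = 0.0034 and 0.30). CD109, PLCB4 and TMEM184A, the brighter ones among the falls, were 2.10-fold, 2.03-fold and 1.99-fold lower, with adjusted p of 0.0011, 0.00089 and 0.00089. Of the 20 genes with the largest rises and falls, 17 had both group means under 5 on the log2 scale (an intensity of 32), where values lie near the lowest the arrays hold, 12 rested on 1 probe and 6 were measured on all 20 arrays. The block on title numbers kept 14 of the 20 calls, and SSTR1 went from -0.99 to 0.05 (adjusted p = 0.92) when its brighter probe alone was used. In runs without 1 sample, SPAG17, LUZP2, IP6K3, ACADL and ICAM5 were called in 13, 11, 3, 18 and 14 of 20 cases.

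Of the 25 selenoprotein genes listed, 12 were measured under a symbol, and 2 of these rose, none fell and 10 did not pass the test. Besides SEPW1, TXNRD1, which encodes the cytosolic thioredoxin reductase, rose 1.21-fold, a log2 fold change of 0.28 ± 0.065 (adjusted p = 0.0080), and was higher in 10 of 10 pairs by title number. SEPHS2, a selenoprotein that makes selenophosphate for selenocysteine synthesis, had a log2 fold change of -0.22 ± 0.078 (adjusted p = 0.0715). GPX3, the extracellular glutathione peroxidase, had 0.49 ± 0.25 (adjusted p = 0.22). With the block on title numbers, the adjusted p of SEPHS2 was 0.0355 and that of GPX3 0.044, which makes 4 selenoprotein genes called. Adjusted over the list alone, SEPHS2 also passed (adjusted p = 0.042), giving 2 genes higher and 1 lower. The plasma selenium carrier SEPP1 gave 0.33 ± 0.235 (adjusted p = 0.415), on 1 probe at low signal (means of 2.29 basal and 2.63 supplemented). MSRB1 gave 0.11 ± 0.096 (adjusted p = 0.55), EPT1 0.08 ± 0.084 and TXNRD2 0.03 ± 0.080. DIO2, DIO3, GPX6 and SEPN1 were measured on 11 to 15 arrays at low signal, with adjusted p from 0.15 to 0.925. The list as a whole was not called by camera (median log2 fold change 0.07, adjusted p = 0.37, and adjusted p = 0.69 with an estimated correlation). The call of TXNRD1 ended with its brightest probe alone (adjusted p = 0.13), with spike-in signal as a covariate (0.098) and with the pair of settings that treat empty cells as missing at random (0.16 and 0.41), while over all 17 alternatives its log2 fold change stayed between 0.19 and 0.32 and its adjusted p ran from 0.0024 to 0.41. GPX1, GPX4 and 9 further selenoprotein genes had no probe with their symbol, and GPX2 and DIO1 were measured on too few arrays; these were not analysed here.

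**Figure D2:**
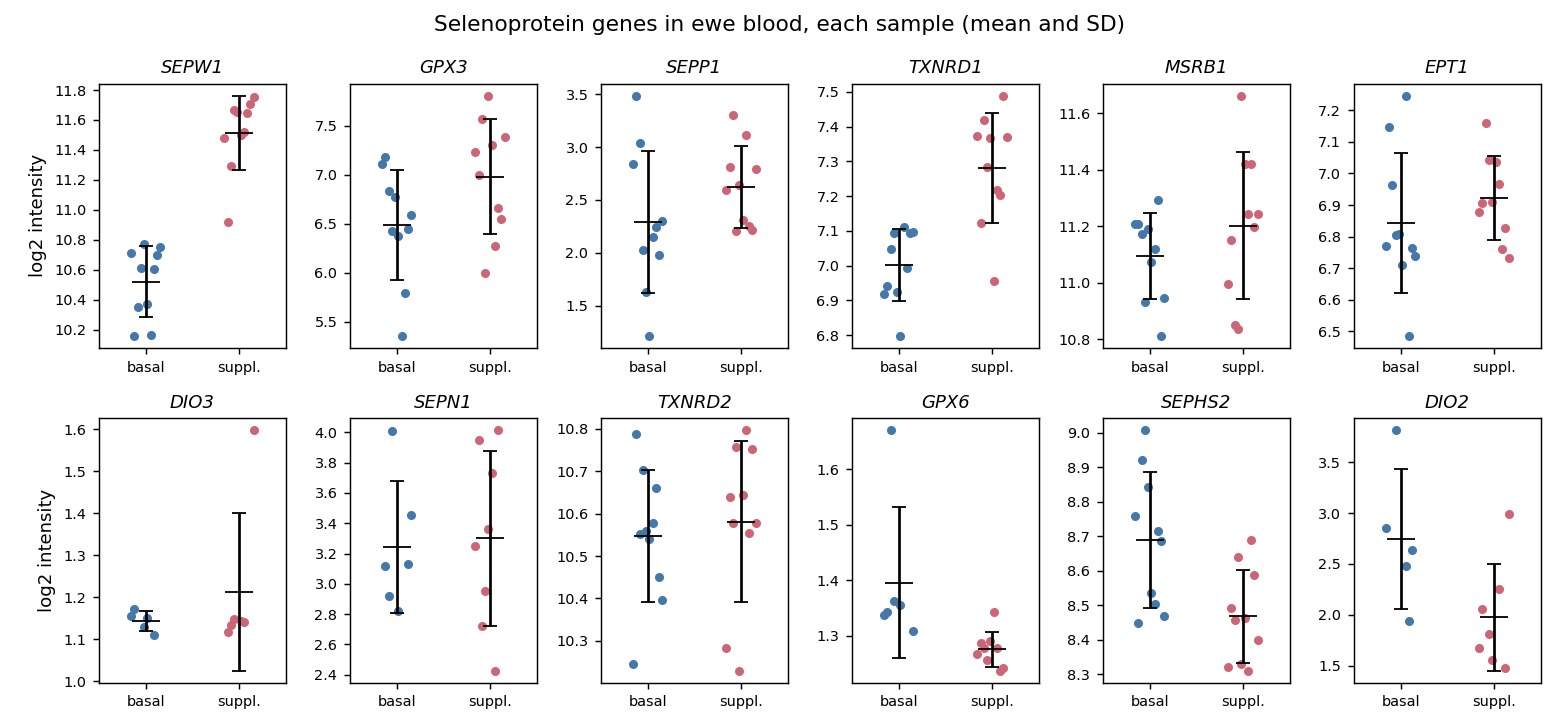
Log2 intensity (vertical axes, each with its own scale) of the 12 measured selenoprotein genes in basal samples at day 0 (blue) and supplemented samples at day 40 (red), ordered by log2 fold change; points are samples, bars the mean and SD. SEPW1 and TXNRD1 passed the test, and the dim genes DIO2, DIO3, GPX6 and SEPN1 lack values for several samples.

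Among 18 measured genes of selenium metabolism and selenocysteine synthesis, 3 rose, 1 fell and 14 did not pass. MAT2B, a regulatory subunit of methionine adenosyltransferase, rose 1.32-fold (adjusted p = 0.0021), SCLY, which encodes selenocysteine lyase, rose 1.28-fold (adjusted p = 0.019), and the seryl-tRNA synthetase gene SARS rose 1.26-fold (adjusted p = 0.046). SEPHS1 fell by 0.28 on the log2 scale at a signal near the lowest values (adjusted p = 0.046, and 0.15 with the block). Of 20 NRF2 targets, 3 rose: SQSTM1, an autophagy receptor gene, by 0.58 on the log2 scale (adjusted p = 0.00071), the ferritin heavy chain gene FTH1 1.16-fold (adjusted p = 0.042) and the pentose phosphate enzyme gene PGD 1.45-fold (adjusted p = 0.046). Of 20 other antioxidant enzymes, GSTM3, measured by 1 probe at low signal, rose 1.93-fold (adjusted p = 0.00565; log2 fold change 0.95, and 0.19 to 1.02 over 17 alternatives, of which 4 ended the call), and GLRX5 and MSRB2 fell by 0.33 and 0.31 on the log2 scale (adjusted p = 0.0081 and 0.023). SOD1 had a log2 fold change of -0.18 ± 0.064 (adjusted p = 0.064). Adjusted over the list alone, 3 genes of selenium metabolism were higher and 4 lower, 4 NRF2 targets were higher and none lower, and 1 other antioxidant enzyme was higher and 3 lower. None of these 3 lists was called by camera (adjusted p = 0.98, 0.38 and 0.43). The median of the selenium metabolism list, -0.04, turned to 0.01 with quantile normalization of all cells. The calls of SARS, SEPHS1 and FTH1 held in 5 of 20 cases each when 1 sample was left out, and that of PGD in 6. With the block, 4 genes of selenium metabolism were higher and 2 lower, 4 NRF2 targets were higher and none lower, and 1 other antioxidant enzyme was higher and 4 lower.

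The mitochondrial respiratory chain list was called lower at day 40 by camera at its preset correlation. Of 56 measured members, 12 fell, 3 rose and 41 did not pass; the median log2 fold change was -0.17 (camera, adjusted p = 0.0020, but p = 0.086 and adjusted p = 0.69 with an estimated correlation). UQCR10, of complex III, was 1.39-fold lower (adjusted p = 0.00040), and COX6B1 and COX7A2, of complex IV, were 1.30-fold and 1.37-fold lower (adjusted p = 0.00155 and 0.00163). ATP5A1, which encodes the alpha subunit of ATP synthase, went the other way and rose 1.24-fold (adjusted p = 0.00087). The list's score was lower at day 40 in 9 of 10 pairs by title number, and adjusted over the list alone 21 members fell and 5 rose. With the block 21 members were lower and 5 higher. Without basal replicates 2 and 7, whose spike-in signal was low, its adjusted p was 0.057 at a median of -0.14.

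A smaller shift was found for cytosolic ribosomal proteins, of which 6 of 53 fell and none rose (median -0.07, adjusted p = 0.046, but adjusted p = 0.955 with an estimated correlation). RPS21, RPL37A, RPS29 and RPS15 fell by 0.26, 0.47, 0.56 and 0.16 on the log2 scale, with adjusted p from 0.024 to 0.042, and adjusted over the list alone no member passed. Of 20 heat shock and chaperone genes, 7 rose and none fell (median 0.05, adjusted p = 0.046, but adjusted p = 0.69 with an estimated correlation). The inducible chaperone gene HSP70.1 rose 1.72-fold (adjusted p = 0.0015), HSP90AB1 1.29-fold (adjusted p = 0.0025), and the chaperonin subunit genes CCT7 and TCP1 1.26-fold and 1.15-fold (adjusted p = 0.0011 and 0.0032). With the block on title numbers neither list was called (adjusted p = 0.14 for both). Leaving out 1 sample ended the call of the ribosomal list in 10 of 20 cases and that of the chaperones in 8, and kept the calls of RPL37A, RPS29 and RPS15 in 10, 9 and 5. With the block 12 ribosomal genes were lower and 7 chaperone genes higher and 1 lower.

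Of 20 glycolysis genes, 4 rose and none fell: PGK1 1.43-fold (adjusted p = 0.00026), PFKL 1.34-fold (adjusted p = 0.0115), GPI 1.24-fold (adjusted p = 0.044) and LDHB 1.11-fold (adjusted p = 0.047); the list was not called (adjusted p = 0.20). Adjusted over the list alone, 5 glycolysis genes were higher. When 1 sample was left out, the call of GPI held in 8 of 20 cases and that of LDHB in 6, and each was called in 9 of 17 alternatives. Of 24 genes of apoptosis and its regulators, 5 rose and 1 fell (adjusted p of the list 0.36). TRADD rose 1.27-fold (adjusted p = 0.0024) and BAK1 1.20-fold (adjusted p = 0.011), and CYCS, which encodes cytochrome c, fell by 0.29 on the log2 scale (adjusted p = 0.0096). Proteasome genes moved both ways, with 4 lower (among them PSMB3, PSMB2 and PSMD7) and 3 higher (among them PSMD13) of 27, and the list's median of 0.03 and mean of -0.05 differ in sign (adjusted p = 0.44). Adjusted over the list alone, 6 apoptosis genes were higher and 1 lower, and 4 proteasome genes were higher and 7 lower. Of 31 cell cycle genes 4 rose, among them MKI67, the proliferation marker Ki-67, 1.26-fold (adjusted p = 0.0047), and MCM4, MCM3 and MCM5 (adjusted p from 0.026 to 0.050; adjusted p of the list 0.43). In the unfolded protein response list HERPUD1 alone of 21 passed, 1.82-fold higher with a supplemented SD of 0.79 against 0.24 in the basal samples (adjusted p = 0.029; list 0.47). Adjusted over the list alone, 4 cell cycle genes were higher and 1 lower, and HERPUD1 did not pass (0.053). With the block, 5 glycolysis genes were higher, 3 proteasome genes were higher and 6 lower, and 4 cell cycle genes were higher and 2 lower. The counts of the apoptosis and unfolded protein response lists stayed the same. Leaving out 1 sample kept the calls of MCM3, MCM5 and HERPUD1 in 14, 4 and 19 of 20 cases.

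NFKB1, which encodes the p50 precursor of NF-kappa-B, rose 1.29-fold (adjusted p = 0.0024) and was the 1 call among 17 inflammatory mediators (list 0.37), in which TNF had a log2 fold change of 0.42 ± 0.18 (adjusted p = 0.16, and 0.0015 with the block). IFI44L fell by 0.35 on the log2 scale (adjusted p = 0.0325), the 1 call among 32 interferon-stimulated genes (list 0.43). Adjusted over the list alone it did not pass (0.098). Of 18 immediate early genes, DUSP1 rose 2.13-fold (adjusted p = 0.016), and NR4A2 and BTG2 fell by 0.37 and 0.45 on the log2 scale (adjusted p = 0.0023 and 0.041); the list was not called (0.91). Of 16 genes of MHC class II and antigen presentation, TAP1 and NLRC5 rose 1.29-fold and 1.28-fold, and HLA-DOB fell by 0.40 on the log2 scale (adjusted p from 0.038 to 0.043; list 0.43). With 1 sample left out, the calls of IFI44L, BTG2, NLRC5, HLA-DOB and TAP1 held in 13, 7, 7, 11 and 8 of 20 cases. With the block, 3 inflammatory mediators were higher, 2 interferon-stimulated genes were higher and 3 lower, 2 immediate early genes were higher and 2 lower, and 4 genes of MHC class II and antigen presentation were higher and 1 lower.

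**Figure D3:**
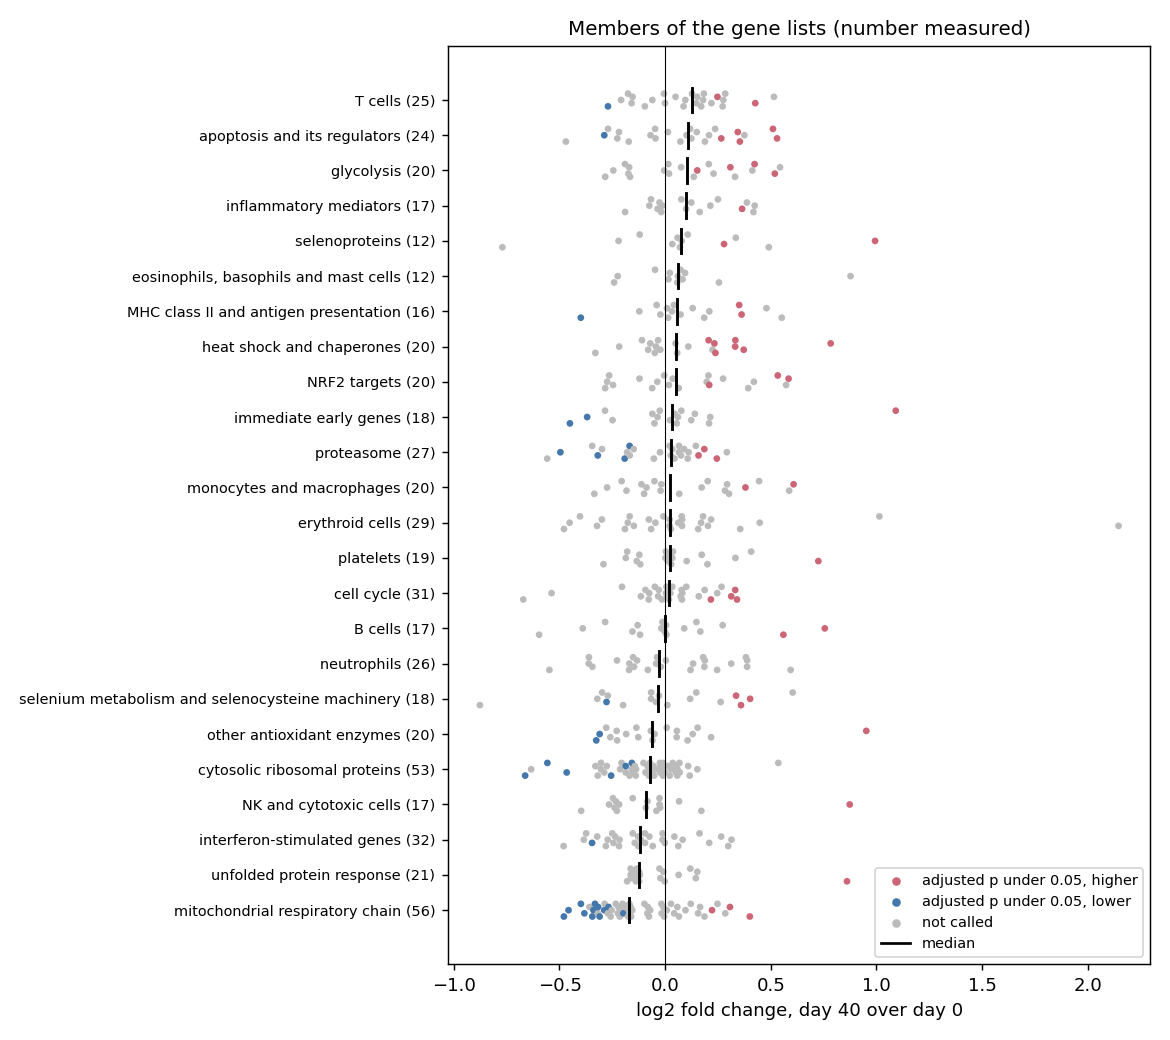
Log2 fold change at day 40 over day 0 (horizontal axis) of each measured member of the 24 gene lists (rows, with the number measured); colour marks members with an adjusted p under 0.05, and the black bar is the list's median. The median of the respiratory chain list was -0.17, the lowest of the 24.

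Markers of blood cell types were compared because whole blood is a mixture. None of the 8 cell type scores differed between the groups: differences ran from -0.09 (NK and cytotoxic cells) to 0.11 (monocytes and macrophages) on the log2 scale, the smallest permutation p was 0.37 and the smallest adjusted p 0.79. Without basal replicate 5 the NK score differed by -0.032, and without supplemented replicate 5 the monocyte score by 0.057. The outermost bound of their 95% intervals was 0.39, for eosinophils, basophils and mast cells. Within the pairs by title number, the outermost bound was 0.31, for monocytes and macrophages. The smallest p within pairs was that of the T cell score, higher in 9 of 10 pairs (exact sign-flip test, two-sided, p = 0.055, adjusted p = 0.44). Single markers did pass. BLK and MS4A1 (CD20), markers of B cells, rose 1.69-fold and 1.47-fold (adjusted p = 0.00089 and 0.023), while the B cell marker MZB1 had a log2 fold change of -0.60 ± 0.31 (adjusted p = 0.23, and 0.0097 with the block). TLR4, a monocyte marker and the endotoxin receptor, rose 1.52-fold (adjusted p = 0.0058), as did APOBR 1.30-fold (adjusted p = 0.027). F13A1, the platelet and monocyte gene for coagulation factor XIII, rose 1.65-fold (adjusted p = 0.00755). Of the T cell markers CCR7 and CD6 rose 1.34-fold and 1.19-fold, and CD28 fell by 0.27 on the log2 scale (adjusted p from 0.029 to 0.037). XCL1 was the 1 call among NK and cytotoxic markers (1 probe at low signal, 1.83-fold higher, adjusted p = 0.0175), with a log2 fold change of 0.87, and 0.31 to 0.99 over 15 alternatives, of which 3 ended the call. Leaving out 1 sample kept the calls of CCR7, CD6 and CD28 in 9, 12 and 17 of 20 cases. With the block, 7 T cell markers were higher and 2 lower, 3 B cell markers were higher and 2 lower, 5 monocyte markers were higher, and 1 NK marker was higher and 3 lower. No marker of neutrophils (26 measured), of eosinophils, basophils and mast cells (12) or of erythroid cells (29) passed; the smallest adjusted p in these lists were 0.063 (FCGR2B), 0.087 (ALOX15) and 0.071 (EPB41). With the block these 3 genes passed (0.0072, 0.0099 and 0.047), and in all 2 neutrophil markers were higher and 2 lower, 1 marker of eosinophils, basophils and mast cells was higher, and 3 erythroid markers were higher and 3 lower. In the erythroid list ALAS2, the erythroid enzyme of heme synthesis, had a log2 fold change of 2.15 ± 0.92 with an SD of 2.25 in the basal samples (adjusted p = 0.14, and 0.018 with the block). By camera no cell type list was called in the main fit (adjusted p from 0.38 to 0.98). With the spike-in signal as a covariate, the T cell list was called higher (median 0.23, camera, adjusted p = 0.0034). That fit rests largely on basal replicates 2 and 7, and the T cell score of basal replicate 2 was the lowest of the basal group (-0.45). The median and the mean differ in sign for B cells and neutrophils, and camera's direction differs from both for erythroid cells and immediate early genes.

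Spike-in RNA, which is added to each sample before labelling, gave a signal 1.65-fold higher in the basal arrays (12.24 ± 0.67 on the log2 scale) than in the supplemented arrays (11.51 ± 0.19; SD, n = 10 each; permutation test, two-sided, p = 0.0058). Basal replicates 2 and 7 were at 11.04 or less, below every other basal sample, of which the lowest was at 12.25. Without these 2 samples 1856 genes changed, 1112 higher and 744 lower, and with the spike-in signal as a covariate 494 genes did, 343 higher and 151 lower. Apart from these 2 samples the groups do not overlap in spike-in signal (basal at 12.25 or more, supplemented at 11.82 or less). The fit with the covariate therefore rests largely on them. Each slide held arrays of 1 group only, 3 slides with basal and 4 with supplemented arrays. With the slide as a random block, 1386 genes changed, 878 higher and 508 lower. Each slide held 1 group, and the same correlation within slides (0.049) was used for all genes. This block therefore cannot remove a difference between slides.

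**Figure D4:**
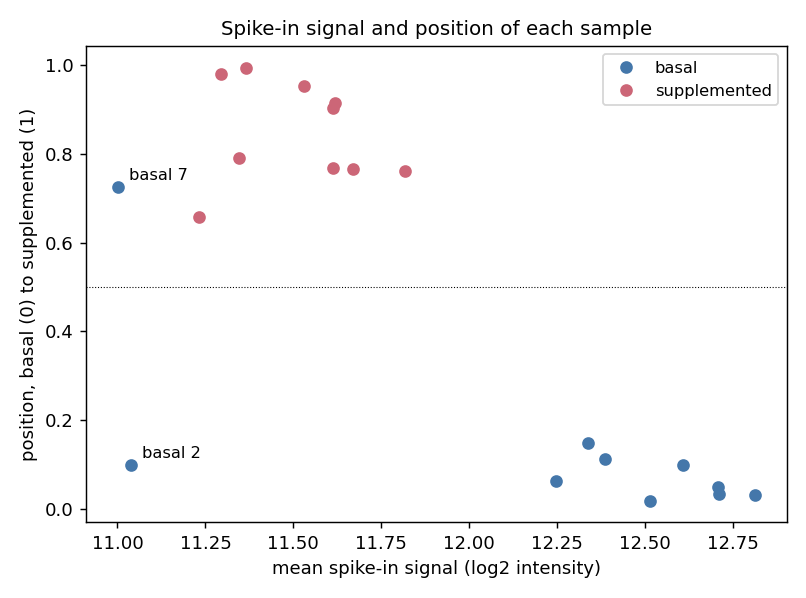
Mean spike-in signal of each array (horizontal axis, log2 intensity) against the sample's position on the genes called without it, from the basal mean (0) to the supplemented mean (1), with basal samples in blue and supplemented samples in red. Basal 2 and basal 7 share a low spike-in signal, at positions of 0.099 and 0.73.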

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

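The tests on basal replicate 7 and those on the bounds of the cell type scores were chosen after those results were seen. Basal replicate 7 stood apart on the difference between the groups itself. On the genes called without basal replicates 2 and 7, it lay at 0.73 on a scale from the basal mean (0) to the supplemented mean (1), while the next highest basal sample was at 0.15. CD109 in this sample was the lowest of the basal group (6.39, next 7.42), and CCND3 (11.44, next 11.09) and PPP4R1 (6.09, next 5.19) were the highest, each toward the supplemented side. Other genes of this sample lay on the basal side, outside the range of the supplemented samples: SEPW1 at 10.16 (lowest supplemented 10.92), PSMB3 at 13.14 (highest 12.98), FAM35A at 8.94 (highest 8.66) and COX7A1 at 9.39 (highest 8.91). They were picked with this sample counted as basal, so they do not settle its label, and its respiratory chain score of 0.16 was the second highest of the basal group. An exchange of labels with a supplemented sample needs a partner on the basal side, and the lowest supplemented sample lay at 0.66. Basal replicate 2, with the same low spike-in signal, lay at 0.099, so a low spike-in signal alone did not bring such a position. The deviations of basal replicate 7 correlated at r of 0.40 with those of its assumed partner, against at most 0.15 in the 90 other combinations of basal and supplemented samples, which argues against a sample of another animal. Another sample of the same ewe, the handling of this sample and a difference of this ewe may each stand behind it and were not tested; leaving it out raised the count of changed genes from 1725 to 2036.

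The other samples far from their group were found among dim genes, PPP4R1 and a score, and are given as values. NRG3 was at 2.65 in basal replicate 5 (next 1.49), ACADL at 1.99 in basal replicate 8 (next 1.48), and OR6Y1 at 3.27 in supplemented replicate 2 (next 1.83). GPX6 was at 1.67 in basal replicate 3 (next 1.36) and at 1.34 in supplemented replicate 6 (next 1.29), and DIO3 at 1.597 in supplemented replicate 10 (next 1.15). PPP4R1 was at 6.06 in supplemented replicate 9 (next 6.19). The score of MHC class II and antigen presentation was at -0.61 in supplemented replicate 5 (next -0.084). In all, 12 of 136 groups of values held such a sample, and chance gives about 1 in 20.

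The 1725 changed genes were not a matter of chance in how the samples were grouped: 1 of 100 splits of the 20 samples into 10 and 10, the real one, gave as many, and the highest of the other splits gave 2. With the block, the real split gave 3135 genes, again 1 of 100 splits that part all 10 assumed pairs, and the highest other gave 9. A difference in RNA input or labelling that the spike-in signal follows stays open, since basal replicates 2 and 7 lay at a mean of 0.41 and on both sides of the midpoint, and each slide held 1 group. A shift in a listed cell type could not be excluded either: the outermost bound of the 95% intervals of the 8 scores was 0.389, against a median absolute log2 fold change of 0.390 of the changed genes. Within the assumed pairs the outermost bound was 0.311, against 0.329 for the genes called with the block, a gap smaller than the SE of the least precise score. The diet, the days between samplings and lactation cannot be separated by this design.

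For the lower respiratory chain genes, a trend with signal level was tested with 10000 random lists matched on mean signal. A share of 0% had a median as low as -0.17, and the central 95% ran from -0.064 to 0.062, which argues against that trend as the cause. The spike-in signal was tested on the list's score, where basal replicates 2 and 7 lay at a mean of -1.31 from the other basal samples (0) to the supplemented samples (1), away from the supplemented side. Their scores (0.158 and 0.156) were the highest of the basal group, so they add to the drop, and without them the list was not called. A test on these samples alone cannot exclude an effect of labelling. The list's own correlation between genes, which ended its call, stays open. So do a change in listed or other cells and a difference between slides, each of which held 1 group. No biological reading is therefore offered.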

How the results depend on the processing

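Alternatives chosen after seeing the data were those on empty cells, the 8 of 10 and 20-array filters, the 16 added before log2, the steps on probes measured on all arrays, the slide, the spike-in signal and leaving out basal replicates 2 and 7. The second table gave identical values. The counts moved by over 1.5 times under 6 settings. Quantile normalization of all cells gave 401 genes (355 higher, 46 lower), 179 by at least 1.5-fold, 1283 probes and 1 selenoprotein gene. Centring each array on its own median gave 161 genes (143 and 18), 153 by at least 1.5-fold, 434 probes and 1 selenoprotein gene; the medians differ with the number of empty cells. The replicate block gave 3135 genes (1668 and 1467), 8055 probes and 4 selenoprotein genes. Empty cells set to 2 gave 901 genes (601 and 300), 218 by at least 1.5-fold and 1 selenoprotein gene. The spike-in covariate gave 494 genes (343 and 151), 145 by at least 1.5-fold, 1450 probes and 1 selenoprotein gene. Adding 16 before log2 left 108 genes by at least 1.5-fold, since it shrinks the folds of dim genes. For the other 4 of these settings the cause was not tested. In every other setting the counts stayed within 1.5 times, from 1386 genes with the slide block to 2202 with array weights, and 1641 by the Wilcoxon test. No cell type score was called in any of its 13 alternatives.

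Leaving out 1 sample gave 1401 to 2036 genes, 881 to 1185 higher, 518 to 851 lower, 295 to 447 by at least 1.5-fold, 3685 to 5236 probes and 2 to 3 selenoprotein genes, with the highest counts of genes without basal replicate 7. List medians then ran from -0.19 to -0.14 for the respiratory chain (called in 20 of 20), from -0.11 to -0.030 for ribosomal proteins (10 of 20), from 0.013 to 0.083 for chaperones (12 of 20) and from 0.060 to 0.11 for selenoproteins (never called).

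The respiratory chain list was called in 15 of 18 alternatives. It was not with each array's own median (-0.14, adjusted p = 0.089), without basal replicates 2 and 7 (-0.14, 0.057) and with an estimated correlation (-0.17, 0.69). The ribosomal list lost its call with each array's own median (-0.049, adjusted p = 0.15), without the dimmest 25% of probes (-0.073, 0.12), with the brightest probe per gene (-0.10, 0.057), array weights (-0.025, 0.33), the replicate block (-0.074, 0.14), empty cells at 2 (-0.055, 0.057), probes on 8 of 10 (-0.073, 0.077) or all 20 arrays (-0.072, 0.11), 16 added (-0.074, 0.055), without basal replicates 2 and 7 (-0.021, 0.26) and with an estimated correlation (-0.074, 0.955). The chaperone list lost its call with each array's own median (0.078, 0.24), without the dimmest 25% (0.053, 0.12), with the brightest probe (0.085, 0.094), array weights (0.023, 0.076), the replicate block (0.053, 0.14), probes on all 20 arrays (0.083, 0.052), without basal replicates 2 and 7 (0.021, 0.082) and with an estimated correlation (0.053, 0.69). Leaving out 1 sample ended the ribosomal call for basal replicates 1, 2, 7, 8 and 9 and supplemented replicates 3, 5, 7, 9 and 10, and the chaperone call for basal replicates 7 and 8 and supplemented replicates 1, 3, 4, 5, 7 and 9. The cause was not tested. Over the 18 alternatives the adjusted p ran from 8.1e-08 to 0.69 for the respiratory chain, 6.1e-07 to 0.955 for ribosomal proteins and 0.0092 to 0.69 for chaperones. Their medians ran from -0.23 to -0.14, from -0.19 to -0.021 and from 0.021 to 0.18.

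With the spike-in covariate, lists not otherwise called passed: interferon-stimulated genes (-0.28, adjusted p = 0.00023), T cells (0.23, 0.0034), glycolysis (0.11, 0.047) and cell cycle (0.13, 0.027). That fit rests largely on basal replicates 2 and 7. Their interferon scores were the highest of the basal group (0.68 and 0.48), and the T cell score of basal replicate 2 was the lowest (-0.45). A called gene changed direction in 3 cases. SSTR1 went to 0.05 with its brightest probe. With empty cells at 2, MSRB2 went to 0.67 and CD6 to -0.52, with the empty spots of 1 probe each. The 10 genes with the smallest p kept their direction in every setting; their calls ended in 5 cases with each array's own median and in 4 with empty cells at 2. The depth of these arrays is their signal over background, which no file gives here; changes of genes near an intensity of 2 rest on values at the end of the scale.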

Other observations

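The tests of gene families that share the start of a symbol were chosen after the lists had been seen; 89 families with at least 15 measured genes were tested with camera. Histone genes had lower values at day 40: of 20 genes whose symbol starts with HIST, 3 fell and none rose, with a median log2 fold change of -0.33 (adjusted p = 0.0016, 5.1e-05 with the block, but adjusted p = 0.58 with an estimated correlation). The other 17 did not pass. HIST1H4K, HIST1H1D and HIST1H4D were 0.71, 0.72 and 0.74 times their basal level (adjusted p = 0.0041, 0.0079 and 0.012). Mitochondrial ribosomal proteins (MRP) went the way of the respiratory chain list, with 9 of 64 lower and 2 higher (median -0.10, adjusted p = 0.017, but adjusted p = 0.58 with an estimated correlation). Among them MRPL48 and MRPL54 were 0.72 and 0.73 times their basal level, and MRPL10 rose 1.29-fold. Subunits of the Mediator complex (MED), which bridges transcription factors and RNA polymerase, had 6 of 27 lower and 1 higher (median -0.11, adjusted p = 0.043, but 0.070 with the block and 0.36 with an estimated correlation), with MED14 0.76 times and MED19 0.77 times their basal level. The families NDUF, NUDT and COX had adjusted p of 0.012, 0.012 and 0.031 toward lower values. With an estimated correlation none of the 3 was called (0.54, 0.21 and 0.225), nor was COX with the block (0.070), and NDUF and COX overlap with the respiratory chain list.

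Protein phosphatase genes (PPP) had higher values, with 10 of 64 higher and 2 lower (median 0.07, adjusted p = 0.043, 0.015 with an estimated correlation, but 0.086 with the block). Besides PPP4R1, PPP6R1 rose 1.44-fold, PPP4C 1.37-fold, PPP2R5D 1.33-fold and PPP2R1A 1.22-fold (adjusted p from 0.00029 to 0.0038), while PPP1CA and PPP4R4 were 0.65 and 0.75 times their basal level (adjusted p = 0.0065 and 0.030). These genes were chosen after their values were seen, and the families were not examined under the other normalizations.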
